A study of Homo sapiens with 166 samples.

How the data were processed

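The series holds RNA sequencing of 166 human breast tumors, 83 labelled as primary tumors and 83 as metastatic tumors. Per the labels, libraries were made from total RNA after removal of ribosomal RNA with a stranded kit and read as pairs of 50 bp on a HiSeq 2500. The mean depth stated in the labels is 136 M read pairs (M for mega). The organ a metastasis was taken from and the tumors that share a patient were not used here, because the labels put only tumor type on each library. The libraries were therefore treated as independent.

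The authors deposited a table of upper-quartile normalized values (unit signal, never negative) with 37517 lines for genes and all 166 libraries. Per the labels and the table, the values are gene quantities scaled by the upper quartile of each library, and the values above 0 had an upper quartile of 933 to 1226 over the libraries. The authors also deposited a log2 table of 20127 genes. It equals the log2 of the normalized values with a constant subtracted per gene, and every blank in it is a 0 among the normalized values. The submitters' processing notes name STAR, Picard 1.64 and Salmon and the genome build hg38, with no parameters. The annotation and the exact order of the steps are not given in the sources used here.

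The sum of a normalized column is not a depth. Low values in each library lay near whole multiples of a smallest step, and an average of 83.7% of them came out within 0.1 of a whole read. Dividing by that step gave an estimate of 3.85 to 64.2 M reads per library, with a median of 20.1 M reads in primary and 23.9 M reads in metastatic libraries. These estimates lie far under the stated 136 M read pairs and were used only as a rough scale and as a covariate. Primary libraries had 16001 to 27270 genes above 0 and metastatic libraries 15267 to 24809. No 2 libraries correlated above 0.982 on the log2 scale, so none was treated as a duplicate.

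The line with no gene name or identifier was left out. It held 3.18% to 46.6% of a library total, with a median of 5.39%. Genes of the Y chromosome, XIST and TSIX (429) were left out as well, which left 37087 genes. Symbols came from the table for 36375 lines, and 1112 of the 1141 lines with an identifier only were matched to a symbol. Coordinates are those of the GRCh38 annotation used for the names. The table does not state how reads were shared between near-identical genes, so values of pseudogenes and paralogs are uncertain.

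Values were analysed as log2(value + 1). The smallest value above 0 was 3.00, so a gene listed at 0 in part of the libraries makes a large step on this scale. Differences between low values above 0 are understated, and those across this step can be overstated. The 20124 genes above 0 in at least 70% of the libraries were tested. Groups were compared with limma (lmFit and eBayes with trend and robust settings), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. FGFR4 and its 3 related receptors were also compared by a two-sided permutation test of the difference of means with 1e+05 resamples. The lists of genes number 37, with 545 genes of which 487 were tested, and cover subtype, pathway, cell type, host tissue and RNA quality. Lists were tested with limma's camera, with a preset correlation between genes of 0.01 and, as an alternative, with a correlation estimated per list. KIT, ERBB2, EGFR and CR2 each stand on more than 1 list.

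Within each group, FGFR4 was correlated with 9 list scores, each the mean of standardized log2 values, which makes a family of 18 relations. Permutation p-values came from 1e+05 resamples. The slope of every other gene on FGFR4 was fitted with limma within each group, and the difference of slopes was tested in a fit of all 166 libraries. A library was said to stand apart on a host tissue list when its mean log2 value for that list lay more than 5 scaled median absolute deviations above the median of the primary libraries. The libraries that stand apart were counted per group and compared by Fisher's exact test. Named genes are the FGF receptors, the 10 largest positive and 10 largest negative differences or slopes among called genes with a mean log2 value of at least 3, and up to 4 members of each list with the smallest p. Where no member of a list was called, its member with the largest difference is named. Items withheld for evaluation are left out of the text. Groups, lists, tests, naming rule and most alternatives were fixed before the data were examined.

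Alternatives covered the pseudocount, the filter, the scaling, the log2 table, array weights, covariates, subsets of libraries, a rank test and a block over neighbouring title numbers. The tests were also run on simulated data. For the group comparison 42.5% of genes changed by 0.5 log2, 82.5% of those changed by 1 and 100% of those changed by 2 were recovered, and 9.26% of the calls were false. Slopes of 0.5 were recovered for 93.8% of genes in primary and 98.5% in metastatic libraries. A list with a simulated shift was found, with 1 other list called beside it. The simulated genes and libraries were drawn independently of each other. The simulations therefore do not show how the tests do with correlated genes or paired libraries. In the data, 99 random regroupings called a median of 9 lists with the preset correlation. Software was Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, statmod 1.5.0 and the data.table package at version 1.17.8.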

Results

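RNA from human breast tumors was profiled, 83 primary tumors and 83 metastatic tumors. The series title links FGFR4, a receptor tyrosine kinase for fibroblast growth factors, to tumor subtype in luminal breast cancer and to metastatic disease. The data were therefore read for which genes differ between metastatic and primary tumors, whether FGFR4 is among them, and which genes follow FGFR4 within each group. Values are upper-quartile normalized gene values, and differences are given as log2(value + 1), metastatic minus primary. The estimated number of reads ranged from 3.85 to 64.2 M per library and was of similar size in both groups, with medians of 20.1 M in primary and 23.9 M in metastatic libraries. Mitochondrial genes made up 0.576% to 87.8% of the total in primary libraries (median 3.40%) and 0.846% to 69.6% in metastatic libraries (median 4.56%). The labels do not say which tumors share a patient, and the libraries were treated as independent, so p-values measure the spread between libraries. Every odd title number is a primary tumor and the next even number a metastatic tumor. Libraries with such neighbouring title numbers correlated across the groups (median r 0.35, against -0.00805 for other combinations). They may be pairs, which these p-values ignore. A block over these pairs called more genes between the groups, 13.8% against 3.82%.

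FGFR4 was higher in metastatic than in primary tumors. Its mean log2 value was 7.05 ± 2.30 in primary (SD, n = 83) and 8.16 ± 2.39 in metastatic tumors (SD, n = 83), and the median normalized value was 139 against 278. The difference of 1.11 (SE 0.36) corresponds to 2.16-fold, with a 95% confidence interval of 1.32- to 3.53-fold, and 69.9% of the metastatic tumors lay above the primary median. The other FGF receptors differed little: FGFR1, often amplified in breast cancer, by 0.04 (SE 0.20), FGFR2 by -0.03 (SE 0.24) and FGFR3 by 0.30 (SE 0.27). The FGFR4 gene (Entrez 2264) lies on the plus strand of chromosome 5 at 177086886 to 177098144 (GRCh38) and codes for protein. It was listed at 0 in 2 primary libraries and 1 metastatic library.

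The two-sided permutation test of FGFR4 gave p = 0.00272, and p = 0.0109 after Benjamini-Hochberg adjustment over the 4 receptors. The same limma fit gave an adjusted p of 0.00919 over the 4 receptors and of 0.0561 over all 20124 genes. With the libraries taken as independent, the difference therefore passed the test among the receptors and missed the threshold among all genes. For FGFR1, FGFR2 and FGFR3 the adjusted p over all genes was 0.953, 0.971 and 0.63. Without the libraries that stand apart on a host tissue list FGFR4 was at 1.02 and was not called over all genes, and FGFR3 turned to -0.33. With a block over neighbouring title numbers FGFR4 passed over all genes, but not in that block without the pairs that stand apart.

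**Figure D1:**
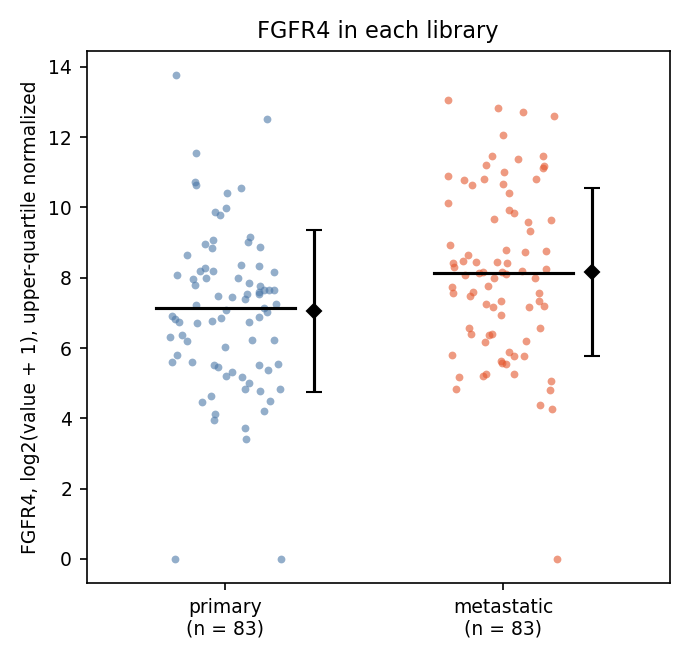
FGFR4 in 83 primary and 83 metastatic tumors, as log2(value + 1) on the y axis, where each point is a library, the horizontal line is the median and the diamond with bars is the mean ± SD. The means are 7.05 and 8.16, and the groups overlap widely.

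The 10 largest decreases in metastatic tumors included genes known from fat, fibroblasts, basal epithelium and muscle. ADIPOQ, the fat cell hormone adiponectin, fell by 3.71 (SE 0.50), SFRP2, a secreted WNT modulator of fibroblasts, fell by 3.22 (SE 0.48) and KRT17, a basal keratin, fell by 2.96 (SE 0.49). TBX5, a T-box transcription factor of limb and heart development, fell by 3.48 (SE 0.36), together with its antisense partner TBX5-AS1 (-2.87). The myosin heavy chains MYH4 and MYH13, known from skeletal muscle, fell by 3.39 and 3.25, and only 1.2% and 2.41% of metastatic tumors lay above the primary median of these genes. Their mean log2 values in metastatic tumors were 1.76 and 2.06, near the bottom of the scale. The skeletal muscle list as a whole was not called, with a median of -0.0015 over 8 genes. LINC01152 (-3.09), AADACL2 (-3.09) and KLK4, a kallikrein protease (-2.86), complete the 10 largest decreases. Each of these 10 genes was also called without the libraries that stand apart on a host tissue list, such as TBX5 at -4.01 and MYH4 at -3.21. Some of these libraries were left out for keratinocyte markers, so the larger fall of the keratin KRT17 (-3.92) can follow from the choice. The size of such decreases depended on the processing. Over the alternatives MYH4 ranged from -4.86 to -1.81, ADIPOQ from -5.03 to -1.02 and KLK4 from -4.14 to -0.87. The calls of ADIPOQ and KLK4 were each lost in 1 alternative.

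The 10 largest increases included genes known from liver and from skin. CYP4F3, which inactivates leukotriene B4, was higher by 1.91 (SE 0.47), MASP1, a protease of the lectin complement pathway, by 1.71 (SE 0.43), ARG1, the arginase of the urea cycle, by 1.70 (SE 0.28), and LIPC, hepatic lipase, by 1.41. FLG2 and KRT10, both of the differentiated epidermis, rose by 1.61 and 1.40. COLEC11, a complement lectin, rose by 1.41, SLC4A4, a bicarbonate cotransporter, by 1.40, and PKNOX2, a homeobox protein, by 1.37. Of ARG1, 85.5% of metastatic tumors lay above the primary median, and of FLG2 53%. Only 2 of the 10 largest increases were still called without the libraries that stand apart, SLC4A4 at 1.81 and PKNOX2 at 1.6, while COLEC11 was at 1.55, ARG1 at 0.82, LIPC at 0.82, MASP1 at 0.80 and CYP4F3 at 0.38 and were not called. FLG2 and KRT10 belong to the list by which these libraries were chosen, so their values without them decide nothing.

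In all, 768 of 20124 genes passed an adjusted p of 0.05 in limma, 20.6% of them higher and the other 610 lower in metastatic tumors. A change of at least 1 log2 was seen in 29 of the higher and 264 of the lower genes. Adjusted p was 1.2e-08 for ADIPOQ, 2.5e-14 for TBX5, 1.0e-19 for MYH4, 8.0e-06 for ARG1 and 0.00657 for CYP4F3. Without the libraries that stand apart (79 primary and 41 metastatic libraries left), 239 genes were called, 41 of them higher. Of the genes called higher in all libraries 13.9% were still called, and of those called lower 27.2%, with fewer libraries, while all but 2 of the former and 609 of the latter kept their direction. These libraries were chosen for high host tissue markers, so lower values of such genes without them follow from the choice. With quantile normalization in place of the authors' scaling, 1264 genes were called, 620 higher and 644 lower.

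Markers of other organs were present in part of the metastatic libraries. The hepatocyte list stood apart in 12 metastatic and 0 primary libraries (adjusted p = 0.00127), the keratinocyte list in 19 and 2 (adjusted p = 6.9e-04) and the erythroid list, genes of red blood cells, in 9 and 0 (adjusted p = 0.00829). With a limit of 8 deviations in place of 5 the erythroid difference was lost, at 3 and 0 libraries (adjusted p = 0.655, and 0.0382 with a limit of 3), while hepatocyte (11 and 0) and keratinocyte markers (17 and 1) still differed. The lung epithelium list stood apart in 2 and 0 libraries, skeletal muscle in 1 and 1, brain in 0 and 1, and bone and mesothelium in none. At least 1 of these 8 lists stood apart in 42 of 83 metastatic and 4 of 83 primary libraries (Fisher's exact test, two-sided, p = 1.3e-11).

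**Figure D2:**
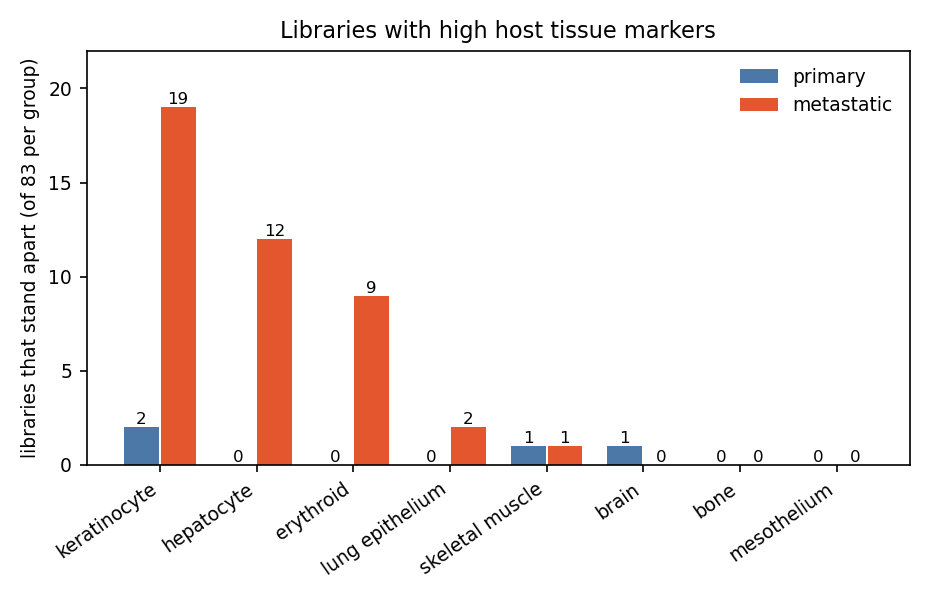
Number of libraries (y axis) in which the mean log2 value of a host tissue list (x axis) lies more than 5 scaled median absolute deviations above the primary median, with bars for 83 primary and 83 metastatic libraries. Keratinocyte (19 against 2) and hepatocyte markers (12 against 0) differ between the groups at each limit used, and erythroid markers (9 against 0) at limits of 3 and 5.

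At the level of lists, all 8 tested hepatocyte genes had positive differences (median 0.88), and 8 passed adjusted over the list alone but 0 over all genes. The size depended on the part of the series. The hepatocyte median was 1.51 for title numbers up to 150 and 0.27 above 150, and the keratinocyte median was -0.16 and 2.06. ALB, serum albumin, was at 1.16 with an adjusted p of 0.284. Of the 5 keratinocyte genes 2 rose over all genes and 2 adjusted over the list alone, and of the 5 erythroid genes 1 and 4. HBB, the beta chain of hemoglobin, rose by 1.34. The preset correlation gave adjusted p-values of 5.6e-06, 1.8e-04 and 8.4e-04 for the hepatocyte, keratinocyte and erythroid lists, all higher in metastatic tumors, and each had an adjusted p = 0.168 with an estimated correlation. In the lung epithelium list 1 gene rose and 1 fell by either adjustment. SFTPB, a surfactant protein, rose by 0.87 and SLC34A2, a phosphate transporter, fell by 1.92, and the list was not called (median -0.08, test direction up, adjusted p = 0.84). Of 8 skeletal muscle genes 1 fell by either adjustment, TNNT3, a fast troponin, by 1.36 (list adjusted p = 0.691). The brain list (median -0.17, adjusted p = 0.691), the bone list (median -0.32, adjusted p = 0.182) and the mesothelium list (median 0.10, adjusted p = 0.889) were not called, and their largest differences were AQP4 at -0.71, DCSTAMP at -0.82 and CALB2 at -1.08, none of which passed over all genes. Adjusted over the list alone, 1 mesothelium gene was lower. Without the libraries that stand apart, DCSTAMP (-1.71) and SLC34A2 (-2.87) were called over all genes. HBB (0.57), SFTPB (0.69), TNNT3 (-1.06), AQP4 (-0.57) and CALB2 (-0.60) were not. These genes belong to the lists by which the libraries were chosen, so lower values among them can follow from the choice.

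Fat, fibroblast and myoepithelial markers were lower in metastatic tumors. Of 12 adipocyte genes 5 fell over all genes and 11 adjusted over the list alone, among them TUSC5, a regulator of glucose transport in fat (-2.50), FABP4, a fatty acid carrier (-1.54), and PLIN1, which coats lipid droplets (-1.01). Of 24 fibroblast and matrix genes 9 fell over all genes and 14 adjusted over the list alone, such as POSTN, the matrix protein periostin (-1.52), FAP, a surface protease of activated fibroblasts (-0.99), and COL10A1, a collagen (-0.65). Of 15 myoepithelial and smooth muscle genes 5 fell over all genes and 6 adjusted over the list alone, including CNN1 and LMOD1, proteins of the contractile apparatus (-1.44 and -0.73), TAGLN (-0.52) and OXTR, the oxytocin receptor (-1.04). Endothelial genes were not called as a list (median -0.08, adjusted p = 0.684, 0 members called by either adjustment), and VWF, von Willebrand factor, was at -0.43 with an adjusted p of 0.252, and at 0.16 without the libraries that stand apart. The epithelial identity list showed no call either (median -0.06, adjusted p = 0.84, 0 members called by either adjustment), with KRT7, a keratin of simple epithelia, at -0.69.

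The adipocyte list gave an adjusted p of 1.8e-11 with the preset correlation and of 0.0371 with an estimated correlation. For the fibroblast list these were 9.1e-12 and an adjusted p = 0.204 with an estimated correlation, and for the myoepithelial list 1.8e-04 and an adjusted p = 0.246 with an estimated correlation. Of the 37 lists, 20 were called with the preset correlation, 9 higher and 11 lower, and 2 with an estimated correlation. In 99 random regroupings of the libraries the preset correlation called a median of 9 lists. The adipocyte, fibroblast and myoepithelial lists were still called without the libraries that stand apart, with the myoepithelial median at -0.19 in place of -0.42, and of the genes named here TUSC5, POSTN and FAP, at -2.10, -1.78 and -0.99. FABP4, PLIN1, COL10A1, CNN1, LMOD1, TAGLN and OXTR, at -1.41, -0.64, -0.53, -0.89, -0.20, -0.26 and -0.67, were not.

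**Figure D3:**
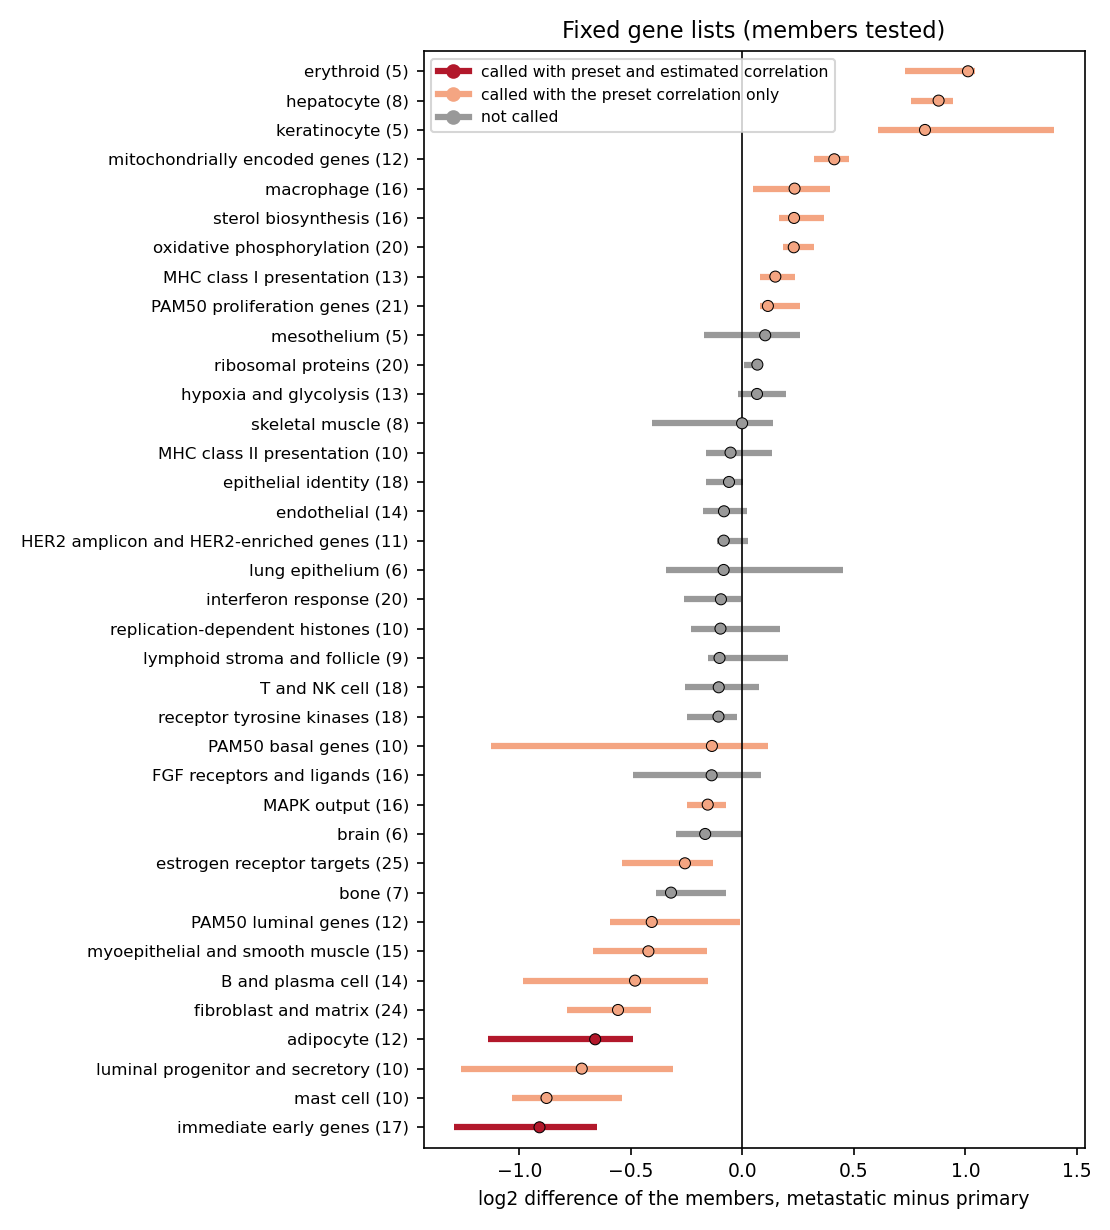
Differences of the tested members of 37 gene lists on the x axis (log2, metastatic minus primary), where points are medians over members, bars span the 25th to 75th percentile and the number of members stands in brackets. Immediate early genes (median -0.91) and the adipocyte list (median -0.66) were called with both correlations.

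Single hormone-related and basal genes fell in metastatic tumors, and no proliferation gene was called. PGR, the progesterone receptor, fell by 1.35 (SE 0.42, adjusted p = 0.048), a call lost in 10 of 18 alternatives, and the estrogen-induced genes GREB1 and SUSD3 fell by 1.33 and 0.95, the SUSD3 call being lost in 11 of 18 alternatives. Of 25 estrogen receptor targets 2 fell over all genes and 6 adjusted over the list alone, and of 12 PAM50 luminal genes 1 and 1. PAM50 names a panel used to assign breast cancers to subtypes. Of 10 PAM50 basal genes 3 fell by either adjustment: KRT17, KRT5 (-2.75), keratins of basal cells, and SFRP1 (-1.38), a WNT antagonist. In the luminal progenitor and secretory list 1 of 10 genes fell over all genes and 4 adjusted over the list alone. The gene called over all genes was KIT, a receptor tyrosine kinase also on the mast cell list, at -0.89. The proliferation list had a median of 0.11, 0 members called by either adjustment, and CCNE1, cyclin E1, at 0.45 with an adjusted p of 0.378. In the list of HER2 amplicon and HER2-enriched genes 0 members were called by either adjustment, and PNMT, a gene near ERBB2, was at -0.62 (list median -0.08, adjusted p = 0.872).

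With the preset correlation the adjusted p was 8.4e-04 for estrogen receptor targets, 0.0345 for PAM50 luminal, 0.0442 for PAM50 basal, 0.00553 for luminal progenitor and 0.0241 for proliferation genes. In the same order the adjusted p was 0.389, 0.452, 0.452, 0.246 and 0.732 with an estimated correlation. Without the libraries that stand apart, PAM50 luminal and proliferation genes were no longer called, with medians of -0.07 and -0.01. PGR, GREB1, SUSD3, SFRP1 and KIT were at -0.92, -0.96, -0.52, -1.23 and -0.73 without these libraries and were not called, while KRT5 was called at -4.57. Some of these libraries were left out for keratinocyte markers, so the larger fall of KRT5, a keratin, can follow from the choice.

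In the lists of FGF receptors and ligands and of receptor tyrosine kinases, 3 ligands and 2 receptors were called, all lower in metastatic tumors. FGF1 fell by 1.12 (SE 0.19), FGF10, a ligand made by stroma for FGFR2 in epithelium, fell by 1.95 (SE 0.43) and FGF18 fell by 1.05 (SE 0.26). Of 16 FGF receptors and ligands 3 fell over all genes, and 1 rose and 5 fell adjusted over the list alone. ETV1, a transcription factor downstream of MAPK signalling, fell by 0.80, the only one of 16 MAPK output genes called over all genes, against 2 lower adjusted over the list alone. Among 18 receptor tyrosine kinases 2 fell by either adjustment, IGF1R (-0.82), the receptor of insulin-like growth factor, and ROR2 (-0.69), a WNT receptor. The MAPK output list was called (median -0.16, adjusted p = 0.0241), with an adjusted p = 0.389 with an estimated correlation, and the call was lost without the libraries that stand apart. The other lists were not called, at an adjusted p of 0.0585 for FGF receptors and ligands and of 0.104 for receptor tyrosine kinases. Without the libraries that stand apart FGF1, FGF10, FGF18, ETV1, IGF1R and ROR2 kept their direction, at -0.70, -1.41, -0.67, -0.48, -0.62 and -0.65, and were not called.

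Immediate early genes, which respond within minutes to growth factors and stress, fell together. NR4A1, a nuclear receptor, fell by 1.62 (SE 0.29), EGR3 by 1.40 (SE 0.27), CYR61, a matrix signalling protein, by 1.24 (SE 0.23) and EGR1, a zinc finger transcription factor, by 1.21 (SE 0.24). Of 17 genes 14 fell over all genes and 15 adjusted over the list alone. The list median was -0.91, with an adjusted p of 9.2e-20 with the preset correlation and of 0.0371 with an estimated correlation. Fibroblast markers (median -0.56) and markers of other organs moved with the same grouping. Without the libraries that stand apart the list and EGR3 (-1.18) were still called, and NR4A1 (-1.21), CYR61 (-0.89) and EGR1 (-0.82) were not.

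FGFR4 correlated with HER2-related genes in both groups and with epithelial genes in primary tumors. In primary tumors it correlated with the score of HER2 amplicon and HER2-enriched genes (r = 0.40, rho = 0.41, permutation p = 2.9e-04, adjusted p = 0.00522), which include ERBB2 and its neighbours on chromosome 17. It also correlated with the epithelial identity score (r = 0.36, rho = 0.37, permutation p = 9.3e-04, adjusted p = 0.00726) and the proliferation score (r = 0.33, rho = 0.26, permutation p = 0.00241, adjusted p = 0.0108). In metastatic tumors the HER2 score passed (r = 0.35, rho = 0.33, permutation p = 0.00121, adjusted p = 0.00726), while the epithelial score did not (r = 0.22, adjusted p = 0.157), nor did the proliferation score (r = 0.09, adjusted p = 0.679). The PAM50 luminal score gave r = -0.12 in primary and -0.07 in metastatic tumors, estrogen receptor targets -0.10 and -0.09, and PAM50 basal genes -0.05 and -0.08. The MAPK output score gave r = 0.06 in both groups, fibroblast genes -0.10 and -0.05, and T and NK cell genes 0.01 and 0.13. None of these passed.

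The family held 18 relations, of which 4 passed. Without the 2 libraries farthest from the median, r was 0.39, 0.34 and 0.23 for the HER2, epithelial and proliferation scores in primary tumors and 0.31 for the HER2 score in metastatic tumors. The rank correlation with proliferation in primary tumors had an adjusted p of 0.0888. No correlation was shown to differ between the groups: the difference was -0.24 for proliferation (permutation adjusted p = 0.853) and -0.05 for the HER2 score. With the epithelial identity score as a covariate 0 of 16 relations passed, and r for the HER2 score was 0.30 in primary and 0.29 in metastatic tumors. Without the libraries that stand apart, r in metastatic tumors was 0.52 for the HER2 score and 0.45 for the epithelial score, which then passed.

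**Figure D4:**
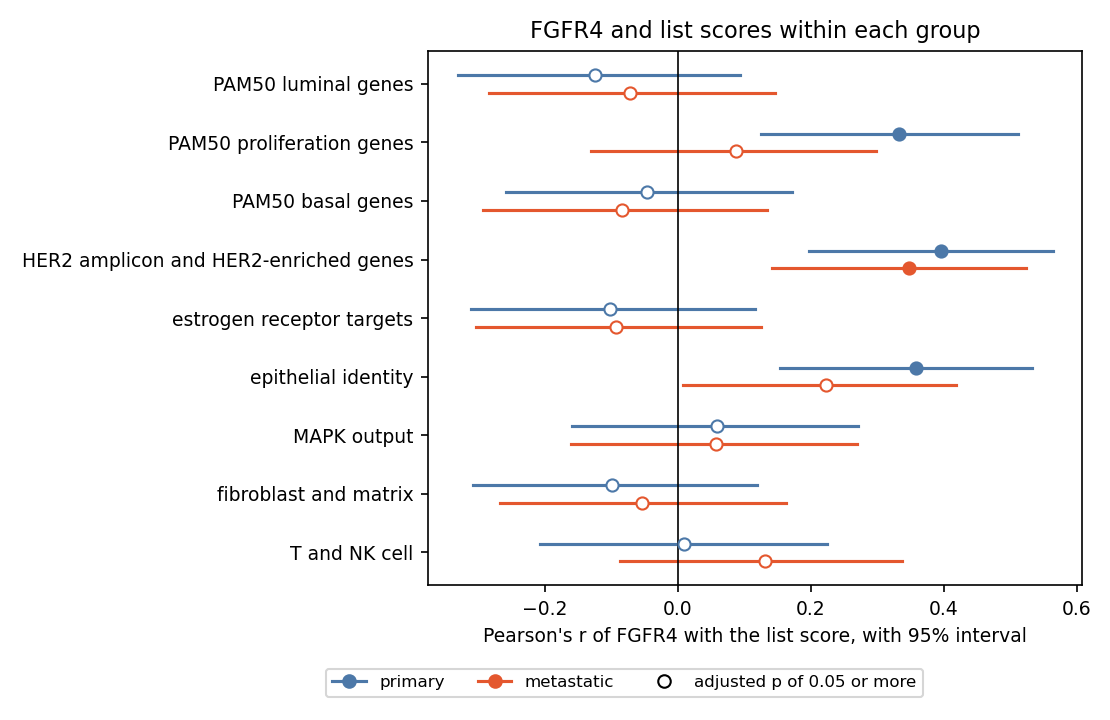
Pearson's r (x axis, no unit) of FGFR4 with 9 list scores (y axis) in 83 primary and 83 metastatic tumors, where points are r, lines are 95% intervals and open points have an adjusted p of 0.05 or more. The HER2 score passed in both groups, with r of 0.40 and 0.35.

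Gene by gene, primary tumors with more FGFR4 had more of ERBB2 and of some genes near it. In primary tumors each log2 of FGFR4 went with 0.30 log2 of ERBB2 (SE 0.07), the HER2 receptor, 0.31 of GRB7, an adaptor protein, 0.24 of ORMDL3, a regulator of sphingolipid synthesis, and 0.25 of MIEN1. The GRB7 call was lost in 8 of 13 alternatives, and the MIEN1 call was lost in 7 and its slope turned in 1. The ERBB2 call was lost in 3 of 12 and the ORMDL3 call in 4 of 13. The largest slopes were those of KRT81, a hair keratin (0.59), SLC9A2, a sodium-proton exchanger (0.52), SERHL (0.51), CNTNAP2, a neurexin family protein (0.46), PAX2, a paired box transcription factor (0.46), UNC5A, a netrin receptor (0.45), KCNK1, a potassium channel (0.44), ADRA2C, an adrenergic receptor (0.44), the antisense transcript MALRD1-AS1 (0.45), and ALOX15B, a lipoxygenase (0.43). SPDEF, an ETS factor of luminal and secretory epithelium, had a slope of 0.23, GATA2, a factor of blood and mast cells, of 0.27 and HPX, the heme carrier hemopexin, of 0.25. Slopes were negative for PPP4R4 (-0.62), SYT9, a synaptotagmin (-0.54), SERPINA3, an antichymotrypsin (-0.46), WFDC2 (-0.46), GATA3-AS1 (-0.44), PRSS50 (-0.41), KCNQ5, a potassium channel (-0.37), NEK10 (-0.33), TPRG1 (-0.33) and GAD1, a glutamate decarboxylase (-0.32). PGR had a slope of -0.39 with an adjusted p of 0.0663.

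In metastatic tumors PGR had the most negative called slope, -0.52 (SE 0.12, adjusted p = 0.0134). The largest slopes were those of C1orf64, an estrogen-regulated gene (0.66), PRODH, the first enzyme of proline breakdown (0.62), the pseudogene CYP4Z2P (0.59), C2orf72 (0.58), ATP13A5 (0.56), LRRC31 (0.53), ALOX15B (0.53), ADAMTS19, a metalloprotease (0.52), SOWAHA (0.48) and the pseudogene ABCC6P1 (0.54). GRB7 (0.31), PNMT (0.48) and TMEM45B (0.26) of the HER2 list were called, as were SPDEF (0.38), DDR1, a collagen receptor kinase (0.14), HPX (0.40), and the endothelial genes CLDN5 (0.27) and EGFL7 (0.18). ERBB2, ORMDL3 and MIEN1 were not called over all genes in metastatic tumors. The calls of DDR1 and EGFL7 lay close to the threshold (limma adjusted p = 0.049 and 0.0498). The respiratory chain genes UQCRQ, ATP5B, SDHA and NDUFB8 had slopes of 0.14, 0.11, 0.09 and 0.08. Negative slopes also belonged to GRPR, the gastrin-releasing peptide receptor (-0.49), LINC01016 (-0.45), CLIC6 (-0.45), TMEM158 (-0.32), PMAIP1, a mediator of apoptosis (-0.30), GJA1, connexin 43 (-0.27), the ribosomal pseudogene RPS20P15 (-0.27), CADM1-AS1 (-0.26) and CCDC170, a coiled-coil protein (-0.25).

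In limma, 180 genes were called in primary tumors (37 of them negative) and 400 in metastatic tumors (369 positive, 31 negative). Of these, 37 positive genes were shared, against 2.62 if the calls were independent, among them GRB7, SPDEF, ALOX15B, HPX, UNC5A and SERHL. Also shared were 3 negative genes, against 0.057: PMAIP1, RPS20P15 and SLC4A7, the last chosen after its values were seen. These expected counts treat the groups and the genes as independent. Libraries with neighbouring title numbers correlated across the groups (median r 0.35) and may be pairs, and genes that vary together can be called together. Either can raise the shared counts, so the excess is not a replication in separate tumors. No gene differed in slope between the groups (0 in limma, 850 at an unadjusted p under 0.05), so the counts of 180 and 400 do not show a difference. Median of ratios scaling turned the split in primary tumors to 56 positive and 73 negative and gave 272 and 73 in metastatic tumors, and quantile normalization gave 56 and 47, and 73 and 36. With ERBB2 as a covariate 49 and 58 genes were called and the slope of MIEN1 in primary tumors was -0.02, and without the libraries that stand apart 1216 genes were called in metastatic tumors.

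As a list, HER2-related genes had positive slopes in both groups. In primary tumors 4 of 11 were called over all genes and 11 adjusted over the list alone, and in metastatic tumors 3 and 9. Of 21 proliferation genes 0 were called over all genes in primary tumors and 18 adjusted over the list alone, with UBE2C, a ubiquitin-conjugating enzyme of mitosis, at 0.23 and an adjusted p of 0.0842. Of 18 epithelial identity genes 1 and 9 were called in primary tumors and 1 and 1 in metastatic tumors. In metastatic tumors 4 of 20 oxidative phosphorylation genes were called over all genes and 12 adjusted over the list alone. In the PAM50 luminal list 0 genes were called over all genes and 5 were lower adjusted over the list alone in primary tumors, and 1 was lower over all genes in metastatic tumors, against 1 higher and 2 lower adjusted over the list alone.

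With the preset correlation 12 lists were called in primary tumors and 10 in metastatic tumors. Lists called in both groups were HER2-related genes (adjusted p = 1.8e-09 and 3.0e-06), epithelial identity, oxidative phosphorylation and sterol biosynthesis with positive slopes, and estrogen receptor targets and fibroblast genes with negative slopes. Proliferation genes and replication-dependent histones (positive) and PAM50 luminal, myoepithelial, MHC class II and brain genes (negative) were called in primary tumors, where 0 histones passed over all genes and 5 of 10 adjusted over the list alone. Endothelial and hepatocyte genes (positive) and erythroid and mitochondrially encoded genes (negative) were called in metastatic tumors. The lowest adjusted p of these lists was 0.372 in primary and 0.778 in metastatic tumors with an estimated correlation, so 0 lists were called that way. With ERBB2 as a covariate the median slope of the HER2 list in primary tumors was -0.02.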

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

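The regroupings, the epithelial covariate and the leaving out of libraries that stand apart were planned. The other tests of explanations in this part were chosen after the group differences had been seen and before their own results were seen, and the test with 4 tissue scores together was added after the tests with fewer scores had been seen. Differences between the groups in FGFR4 slope brought 9 lists to this part, each called by camera with the preset correlation although no single gene was called. For each list the median over its members of the difference of slopes, metastatic minus primary, is given. This median was -0.12 for PAM50 proliferation genes (adjusted p = 1.1e-06), -0.14 for mitochondrially encoded genes (1.1e-06), 0.20 for hepatocyte genes (4.6e-04), 0.10 for MHC class II (5.1e-04) and 0.0937 for MHC class I presentation (1.2e-04). It was 0.0799 for myoepithelial and smooth muscle genes (0.0112), 0.0642 for endothelial genes (6.7e-04), 0.0672 for T and NK cell genes (0.0284) and 0.0717 for macrophage genes (0.0041). With an estimated correlation the adjusted p of these lists was 0.876 to 0.98, so none was called that way. The line with no gene name or identifier, a signal not analysed here, held up to 46.6% of a library total.

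Random regroupings of the libraries, 99 beside the real one, set a scale for these counts. The regroupings did not keep neighbouring title numbers together, so they ignore possible pairs. The real grouping was the only 1 of 100 with as many called genes (768, highest other 2), and the only 1 of 100 with as many called lists (20, highest other 19). Every other grouping called at least 1 list, with a median of 9, so a call of a single list with the preset correlation is weak evidence. A list p as small as the real one came by regrouping for proliferation genes in 53 groupings, for MHC class I in 29, for macrophages in 28 and for PAM50 basal genes in 27, against 0 for adipocyte, 1 for oxidative phosphorylation and 2 each for immediate early, fibroblast, mast cell and sterol genes. Between these lay, among others, myoepithelial (10), mitochondrially encoded (11), estrogen receptor target (12) and PAM50 luminal genes (21). For genes with a different FGFR4 slope the real count was 0, which all 100 groupings reach by construction, so this comparison decides nothing. The highest other count there was 529, with a median of 0, which a structure of the libraries or correlation between genes can give, and neither was tested.

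FGFR4 was higher in metastatic tumors by 1.11 log2. Hepatocytes express FGFR4, and 12 metastatic libraries carried hepatocyte markers, with a median FGFR4 value of 556 against 272 in the other metastatic and 139 in the primary libraries. Subtracting the most FGFR4 that such cells can bring, judged from the lowest ratio of FGFR4 to ALB, left 0.94 (fall 0.17, bootstrap SE 0.0873), covariates for depth left 1.12 (fall -0.00472, SE 0.137), and the epithelial identity score as a covariate left 1.16 (fall -0.0485, SE 0.0925). Depth was of similar size in both groups and, as far as these rough estimates measure it, is not the cause of more than 50%. Hepatocytes are not either, if they all share 1 ratio of FGFR4 to ALB. The epithelial identity list was not higher in metastatic tumors (median -0.06), so more epithelial cells were not seen. Its score as a covariate could therefore hardly lower the difference, and that test adds nothing. Without the libraries marked by any host tissue list FGFR4 was at 1.02 and was not called over all genes. FGFR4 in cells of other organs that these lists miss, the choice of tumors for the series and a change in the tumor cells with metastasis stay open and were not tested.

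Genes at least 1 log2 lower in metastatic tumors number 264, with a median of -1.33. The fibroblast score as a covariate left -1.04 (78.2%, bootstrap SE 5.96), the adipocyte and myoepithelial scores left -0.90 (67.6%, SE 5.78), and leaving out the libraries that stand apart left -1.22 (92%, SE 8.23). Fibroblast, adipocyte, myoepithelial and endothelial scores together, a measure of breast tissue around the tumor cells, left -0.85 (63.8%, SE 6.2). The libraries that stand apart are therefore not the cause of more than 50%. With the scores as covariates more than 50% was left as well. List scores are noisy proxies of cell content, so the part of these tissues could be larger than measured, and the covariates cannot set a limit on it. Less breast tissue, as a partial or a main cause, and a difference of the tumor cells stay open, and the latter was not tested.

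Immediate early genes were lower in metastatic tumors, with a median of -0.91 over 17 genes. Depth covariates left -0.88 (96.5%, bootstrap SE 11.1), so depth, as far as these rough estimates measure it, is not the cause of more than 50%. Leaving out the libraries that stand apart left -0.68 (74.6%, SE 17.4) and the fibroblast and endothelial scores as covariates left -0.68 (75%, SE 12.9), and neither decides. These genes respond within minutes to the handling of tissue, and the labels give no time from removal to freezing, so handling that differed between primary and metastatic tumors is a possible explanation that was not tested. It cannot be told apart here from tissue content or from a difference of the tumors.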

How the results depend on the processing

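Depth covariates, voom, leaving out the 2 libraries over 50% mitochondrial, libraries with fewer or more genes above 0, the epithelial covariate on the FGFR4 relations, and the block without pairs that stand apart were tests chosen after the data had been seen. The cause of the changes below was not tested. Libraries stand apart by their host tissue markers, so changes of those lists and of ALB without them follow from the choice and decide nothing. Of 81 named genes compared between groups, 13 kept direction and call under every alternative, as did 2 of 37 lists and none of the 59 named slopes. Of 1442 gene values under alternatives 1198 stayed the same, 16 were stronger, 12 turned and the others were weaker. For lists 566 of 681 stayed the same, 58 were weaker, 20 stronger and 37 turned, and for slopes 441 of 756 stayed the same, 313 were weaker and 2 turned. No scaling moved the median of all genes by over 0.1 log2. The epithelial covariate was not applied to the epithelial list itself. At the estimated depth, genes with low values carry few reads, and the size of differences among them depends on the pseudocount and on values at 0.

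Numbers of called genes are given as a percentage of the genes tested, and changes were judged on the numbers themselves. Between groups 3.82% (768 genes) were called, against 6.28% with quantile normalization, 6.09% with array weights, 1.19% without the libraries that stand apart, and 0.755% and 0.571% in the libraries with title numbers up to 150 and above 150. In 11 other fits 576 to 1013 genes were called. FGFR4 passed over all genes with a pseudocount of 10 (1.01), quantile normalization (1.17), array weights (1.31), the epithelial covariate (1.16), without the mitochondrial libraries (1.16) and in a rank test (1.01). Over all alternatives it was 1.01 to 1.31, with adjusted p from 0.00323 to 0.43. FGFR1 turned to -0.0109 without the mitochondrial libraries. FGFR2 turned to 0.0145 with array weights, 0.0383 for title numbers up to 150 and 0.0281 with voom. PNMT turned to 0.0693 in the log2 table and ALB to -0.0428 in the rank test. FGFR3 was -0.33, VWF 0.16 and ALB -0.10 without the libraries that stand apart.

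The count of 20 called lists became 11 in the log2 table, where fewer lists could be tested, 13 without the libraries that stand apart and 2 with an estimated correlation. It was 15 to 23 otherwise. The direction of the list test turned in these cases, given with the median. Stand-apart libraries left out: proliferation -0.0080, endothelial 0.0470, MHC class II -0.10, lymphoid stroma -0.18, lung -0.13, keratinocyte -0.18 and mesothelium -0.14. Title numbers up to 150: HER2 -0.0831, epithelial 0.00142, interferon -0.0435, lymphoid stroma -0.16, brain -0.15 and skeletal muscle 0.0451, and above 150: MHC class II 0.0162, mesothelium 0.0687 and histones 0.0233. Array weights: epithelial -0.0350, endothelial -0.00683, T and NK cell -0.0791 and histones -0.00501. Quantile normalization and depth covariates: T and NK cell 0.0423 and 0.0398. Voom: mesothelium 0.11 and histones 0.0400. The fry test: mesothelium 0.10. Histones also turned with a pseudocount of 10 (-0.0495) and the epithelial covariate (-0.0416).

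Of 18 FGFR4 correlations 4 were called, against 2 in the log2 table, 0 in the libraries with fewer and 1 in those with more genes above 0, and 0 with the epithelial covariate. Other alternatives called 4 or 5. In primary tumors r turned in libraries with more genes for PAM50 luminal (0.0343), basal (0.0600), estrogen receptor targets (0.11), fibroblast (0.11) and T and NK cell genes (-0.0829). The last also turned with a pseudocount of 10 (-0.0646), median of ratios (-0.0257), quantile normalization (-0.0870) and the log2 table (-0.15). MAPK output turned in primary tumors with median of ratios (-0.0335), quantile normalization (-0.00593), fewer genes (-0.0381) and the epithelial covariate (-0.00083), and in metastatic tumors with quantile normalization (-0.0399) and the log2 table (-0.00314). Proliferation in metastatic tumors turned to -0.0193 with the epithelial covariate.

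Slopes in primary tumors were called for 0.895% of genes, against 2.39% with a pseudocount of 0.1, 0.362% without the filter, 0.512% with quantile normalization, 0.393% in the log2 table, 0.244% with the ERBB2 covariate, 0.0199% and 0.0248% in libraries with fewer and more genes, and 0.0696% with the epithelial covariate. In metastatic tumors they were called for 1.99%, against 5.48% with a pseudocount of 0.1, 0.711% with one of 10, 0.542% with quantile normalization, 0.348% in the log2 table, 6.04% without the libraries that stand apart, 0.288% with the ERBB2 covariate, 0.104% and 0.0149% in libraries with fewer and more genes, and 0.76% with the epithelial covariate. Without the filter the share in metastatic tumors was 0.828%, as more genes were tested. With ERBB2 as a covariate, MIEN1 turned to -0.0167 and the HER2 list in primary tumors to -0.0154, and CLDN5 turned to -0.0082 in libraries with more genes. Of 12 and 10 called slope lists 0 and 0 were called with an estimated correlation, and 6 of the metastatic lists with the ERBB2 covariate. At limits of 3 and 8 deviations 9 and 2 primary libraries stood apart.

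Every odd title number is a primary tumor and the next even number a metastatic tumor, though the labels do not say what the numbers mean. This order and the correlations below give reason to read neighbouring numbers as pairs. The main tests, the regroupings and the bootstraps ignored them. Over 83 neighbouring pairs the median r of deviations from the group mean was 0.35, against -0.00805 for other combinations, and 59 of 83 libraries in each group correlated best with their neighbour (1 expected). Of the 83 pairs 78 had r over 0.1, and the lowest r was -0.0169. With these pairs as a block, 13.8% of genes (2784) were called and FGFR4 passed at 1.11, and 1.70% (343) were called without the pairs that stand apart. In that last fit FGFR4 was 1.15 and did not pass over all genes (adjusted p = 0.179), FGFR3 was -0.0346, VWF 0.36 and ALB -0.14, and lists turned for proliferation (-0.0225), HER2 (0.0729), epithelial (0.0666), endothelial (0.16), MHC class II (-0.19), lymphoid stroma (-0.25), lung (-0.00081), keratinocyte (-0.0358), mesothelium (-0.0926) and histones (0.0406). Differences within pairs gave 2 called correlations of 9.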

Other observations

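Of 20 oxidative phosphorylation genes 3 rose over all genes and 10 adjusted over the list alone, among them ATP5B, part of the ATP synthase (0.44), UQCRQ, of respiratory complex III (0.42), and COX4I1, of cytochrome c oxidase (0.31). The list had a median of 0.23 and an adjusted p of 3.6e-10, and an adjusted p = 0.168 with an estimated correlation. Of 16 sterol biosynthesis genes 2 rose over all genes, including MSMO1, a sterol oxidase (0.57), and 4 rose adjusted over the list alone (median 0.23, adjusted p = 6.8e-07, and adjusted p = 0.168 with an estimated correlation). Of 12 mitochondrially encoded genes 0 rose over all genes and 5 adjusted over the list alone (median 0.41, adjusted p = 5.5e-06, and adjusted p = 0.351 with an estimated correlation), with MT-CO1 at 0.57. Hypoxia and glycolysis genes (median 0.07, adjusted p = 0.114, P4HA1 at 0.31), ribosomal proteins (median 0.07, adjusted p = 0.102, RPS14 at 0.24) and replication-dependent histones (median -0.10, adjusted p = 0.889, HIST1H4H at 0.35) had 0 members called by either adjustment. The called lists of this paragraph were still called without the libraries that stand apart, and its genes called with all libraries were not, with ATP5B at 0.27, UQCRQ at 0.30, COX4I1 at 0.23 and MSMO1 at 0.49.

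Of 10 mast cell genes 5 fell over all genes and 6 adjusted over the list alone. They include MS4A2, a chain of the IgE receptor (-1.44), SIGLEC6 (-1.08), TPSB2, a tryptase (-1.05), and KIT (-0.89), which is also on the luminal progenitor list. The list had a median of -0.88, an adjusted p of 1.1e-06, and an adjusted p = 0.168 with an estimated correlation. MS4A2, SIGLEC6 and TPSB2 were also called without the libraries that stand apart, while KIT (-0.73) was not. JCHAIN, which joins antibody units, fell by 1.70, the only one of 14 B and plasma cell genes over all genes, against 4 adjusted over the list alone (median -0.48, adjusted p = 0.00938, and adjusted p = 0.452 with an estimated correlation). C1QA, a complement component (0.61), and MRC1, the mannose receptor (0.59), were the 2 of 16 macrophage genes that rose by either adjustment, at adjusted p-values of 0.0487 and 0.0497 and with calls lost in 11 and 9 of 18 alternatives (list median 0.23, adjusted p = 8.1e-04, and adjusted p = 0.452 with an estimated correlation). MHC class I presentation was called (median 0.15, adjusted p = 0.00957, and adjusted p = 0.534 with an estimated correlation) with 0 members called by either adjustment and PSMB8, of the immunoproteasome, at 0.39. Without the stand-apart libraries the macrophage (median 0.0830) and MHC class I lists, JCHAIN (-1.58), C1QA (0.41) and MRC1 (0.26) were not called. The lists of T and NK cells (median -0.11, adjusted p = 0.868, SH2D1A at -0.66), interferon response (-0.10, adjusted p = 0.513, CXCL11 at -0.45), MHC class II (-0.05, test direction up, adjusted p = 0.759, CTSS at 0.38) and lymphoid stroma (-0.10, test direction up, adjusted p = 0.759, CCL19 at -0.66) were not called, and 0 of their members were by either adjustment. With the libraries that stand apart left out, CTSS was at 0.13 and CCL19 at -1.21, neither of them called.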
